A study of Escherichia coli K-12 with 6 samples.

How the data were processed

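Expression data from 6 arrays of *Escherichia coli* K-12 MG1655 were analysed, a laboratory strain whose chromosome is fully sequenced. Total RNA came from 3 wild-type cultures and 3 cultures of a strain lacking the whole *rpoS* gene, which encodes the sigma factor that directs RNA polymerase to general stress and stationary-phase genes. Per the labels' protocols, each culture began from its own colony, was diluted to an OD600 of 0.0001 in LB, was shaken at 200 rpm and 37 °C, and was collected at an OD600 of 0.3. By then it had grown exponentially for 8 generations or more. RNA was released in boiling lysis buffer and purified with hot acidic phenol, labelled with biotin and hybridised to the Affymetrix E. coli Antisense Genome Array, on which a probe set of short oligonucleotides reads out each gene or intergenic region.

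The authors deposited 1 value per probe set and array, and these values were read as log2 signals from their range, which ran from 0 to 13.9. How the probes were summarised and scaled, with which software and against which genome build, is not given in the sources used here. A few values per array, between 1 and 4, were exactly 0. The deposited medians over all probe sets were 8.95, 9.13 and 8.88 on the wild-type arrays and 8.65, 8.45 and 8.64 on the mutant arrays, so the table had not been brought to a common distribution. The main scaling was chosen by a rule written before the data were examined: the deposited log2 values were to be used unless their medians differed, and quantile normalization otherwise. Quantile normalization over all 7312 probe sets was therefore used.

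Probe sets were named through the platform annotation and the RefSeq gene table of MG1655 (assembly ASM584v2), matched by Entrez gene number. Of the probe sets, 2886 were intergenic and 81 were controls, 50 of them for sequences foreign to *E. coli* (among them *Bacillus*, phage P1, phage M13 and plasmid F genes). Among the others, 4192 matched 1 gene, 41 matched several and 112 matched none. The locus tag inside the probe set's own identifier was that of the matched gene in 4101 cases and another in 91. Where several probe sets matched a gene, the one with the highest mean signal was kept, which left 4148 genes. Only names and the order of genes were taken from the gene table, not coordinates, because the build behind the array was not stated. Every one of the 6 value columns carried a sample's own label, and 0 columns were left unassigned.

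Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided), mutant minus wild type, without covariates. A gene passed the threshold when its Benjamini-Hochberg adjusted p over all genes tested was under 0.05. Intergenic probe sets were tested in a fit of their own. There were 40 gene lists, with 881 different genes of which 868 were measured, fixed beforehand and tested with limma's camera at its preset correlation of 0.01, adjusted over the lists. Each list was also tested with camera's estimated correlation and with fry, which asks whether a list's genes moved on balance one way and does not compare them with other genes. The smallest p that an exact permutation of 3 against 3 arrays could give is 0.1, so all p-values rest on limma's pooled spread. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

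The genes named in the text follow a rule fixed beforehand. It took *rpoS* and its measured neighbours, the 12 largest decreases and 12 largest increases past the threshold with groups that did not overlap, and per list up to 4 members past the threshold in order of size, or the largest change where none passed. The text names members from among these, in places grouped by direction and not always every one. The list of *rpoS* neighbours, as fixed, also held *ubiX* and *ubiD*, which lie 444 and 1161 genes away in gene order. Genes named outside the rule are marked as chosen after their values were seen. On values simulated for this comparison over 4148 genes, in 5 runs with 200 genes changed in each, the procedure recovered 58.0% of changes of 0.5 on the log2 scale, 93.6% of changes of 1, 98.0% of changes of 2 and 99.6% of changes of 3. Of its calls, 6.02% were false. The simulated values had independent noise in each gene and no shift or trend shared by the genes of an array. This share therefore does not describe the calls on the real arrays, which held such trends.

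Other settings listed at that stage were centring each array on the median of its gene probe sets, leaving out the 25% of genes with the lowest signal, adding an offset of 50 to the linear signal, an intensity trend or robust hyperparameters in eBayes, array weights, a replicate block, leaving out each array in turn, adjusting genes and intergenic probe sets together, keeping all probe sets of a gene, asking for a change of at least 2-fold, and the other list tests. After the data had been seen, 5 more were added: the values as deposited, centring on the foreign control probe sets, quantile normalization over gene probe sets alone, leaving out the genes from *ynaJ* to *ydbK*, and removing from each deposited array a loess trend on mean signal and on distance from the replication origin in gene order. The last gives no intergenic values. The distance from the origin was counted in genes from the interval between *mnmG* and *mioC*.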

Results

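Gene expression was compared between wild-type *E. coli* MG1655 and an *rpoS* deletion mutant during exponential growth in LB, 3 arrays per strain. Series and sample labels state the aim of identifying the genes that depend on RpoS in early exponential growth, a phase in which this sigma factor is usually scarce. All changes are given as log2 fold change, mutant minus wild type, after quantile normalization, with the limma standard error (SE). Over genes, replicate arrays correlated at between 0.980 and 0.995 within the wild type and between 0.9825 and 0.9932 within the mutant, and arrays of different strains at between 0.929 and 0.967. No pair of arrays held the same values at more than 3 probe sets. Cultures came from separate colonies, so the spread between arrays includes biological variation.

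The deleted gene itself was lower on each mutant array. The *rpoS* probe set (b2741) read 10.61, 10.72 and 10.29 in the deposited values of wild-type replicates 1, 2 and 3, against 7.89, 7.72 and 7.70 in the mutant. Its change was -2.45 (SE 0.115, n = 3 per strain, limma adjusted p = 0.00018), a 5.47-fold lower signal. The remaining mutant signal was still above the medians of the foreign control probe sets on the same arrays, 6.29, 6.38 and 6.22. Of 15 measured genes of the neighbour list that lie beside *rpoS* on the chromosome, 5 fell, 0 rose and 10 did not pass. The list held 2 further genes that lie elsewhere by their locus tags, *ubiX* and *ubiD*, and its camera test covers all 17 (adjusted p = 0.0715, and adjusted p = 0.85 with an estimated correlation; adjusted p = 0.0488 without mutant replicate 1). In the whole list 2 fell without mutant replicate 3, and 3 fell without wild type replicate 2, wild type replicate 3 or mutant replicate 2 or with the signal and position trend removed. Those that fell were *pphB*, a protein phosphatase gene (-1.01, SE 0.197), *ygbM* (-0.65, SE 0.125), *ygbK* (-0.45, SE 0.133), *ygbJ* (-0.42, SE 0.0812) and *mutS*, encoding a DNA mismatch repair protein (-0.27, SE 0.0706). Of the genes elsewhere, *ubiD* of ubiquinone synthesis rose (0.54, SE 0.102; -0.06 with control centring) and *ubiX* had a value of -0.02 (0.02 with array weights). *nlpD*, the lipoprotein gene directly upstream of *rpoS*, had a value of -0.18 (SE 0.0864) and did not pass; it lay at 0.16 with median centring.

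Across 4148 genes, 1119 passed the threshold, 525 lower and 594 higher in the mutant, and 113 of them changed at least 2-fold, 51 lower and 62 higher. At an unadjusted p under 0.05 there were 1768. The 3 mutant values lay wholly on one side of the 3 wild-type values in 2069 genes, 49.9% of those tested, where chance gives 10% for a single gene. All genes share the same 6 arrays, so a difference between whole arrays can separate many at once. The excess therefore does not count the genes that differ beyond chance. The split of directions depended on the scaling. With the values as deposited, 1735 genes passed, 1615 lower and 120 higher, and centring on the foreign control probe sets gave 1245 lower and 16 higher. The median change of all genes was -0.25 and -0.62 under these scalings and 0.02 after quantile normalization. Control centring leaned on wild type replicate 2. The deposited foreign medians were 6.02, 5.459 and 6.295 on wild-type replicates 1, 2 and 3, and 6.285, 6.381 and 6.222 on the mutant ones. Results with control centring carry this limit throughout. All 525 lower genes, but only 117 of the higher ones, passed in the same direction with the values as deposited. Calls were also arranged along the chromosome: 76.8% of the lower genes and 21.2% of the higher genes lay among the 50% of genes nearest the replication origin in gene order. Of the increases named below, those of *narU*, *ubiD*, *pta*, *umuC*, *cspB*, *trpC*, *ilvB*, *artM*, *deoC*, *phoH*, *nac*, *glpF* and *lrp* did not pass with the values as deposited. In 71 genes past the threshold, 55 lower and 16 higher, the dimmer strain's mean lay below its median of foreign control probe sets (5.65 in the wild type and 6.73 in the mutant after quantile normalization), so the sizes of these changes are uncertain and have no order. Among the genes named below this held for *dcuD*, *acrF*, *rclB*, *ygeH*, *yibG*, *dctR*, *gadE*, *gadB*, *tdcA*, *zntB* and *uspE*, and for *rcbA*, *ralR* and *cspB* the means of both strains lay below. The mutant mean of *nac*, its brighter strain, also lay below.

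**Figure D1:**
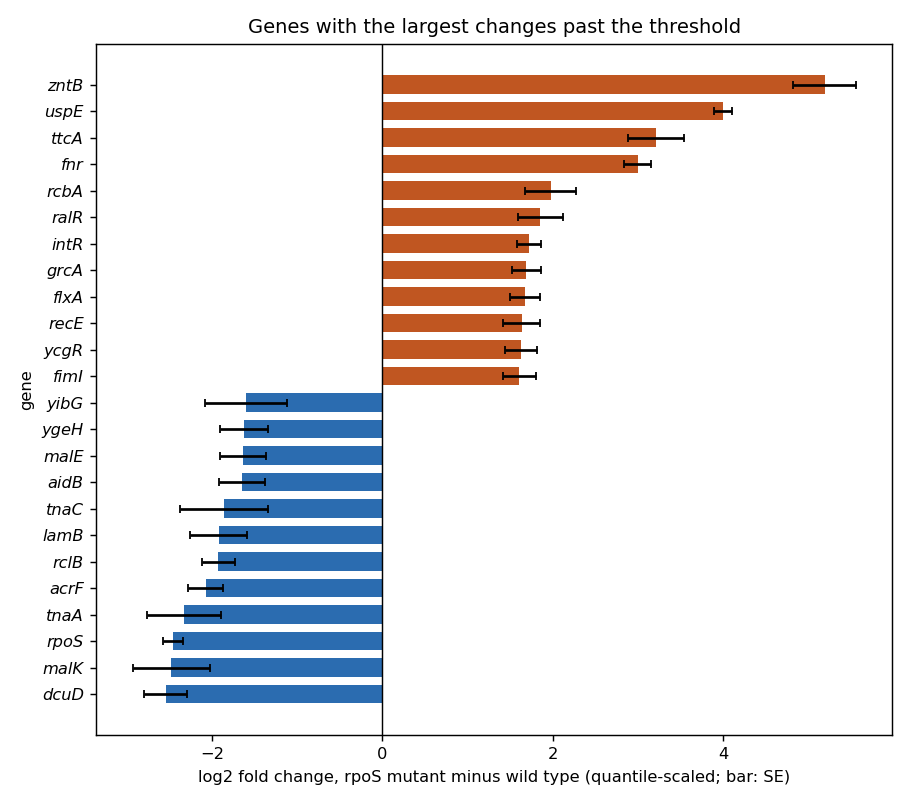
Log2 fold change (horizontal axis, rpoS mutant minus wild type) of the 12 largest decreases and 12 largest increases past the threshold, with bars for the mean change and whiskers for the SE over 3 arrays per strain. Bars ran from -2.54 for dcuD to 5.19 for zntB, and for dcuD, acrF, rclB, ygeH, yibG, zntB, uspE, rcbA and ralR at least the dimmer strain lay below the foreign control median, so their lengths have no order.

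Maltose uptake and tryptophanase genes were among the largest decreases with both strains above the foreign control medians. *malK*, *lamB* and *malE*, which encode the ATPase, the outer membrane porin and the binding protein of maltose uptake, fell by 2.47 (SE 0.456), 1.92 (SE 0.335) and 1.63 (SE 0.270). The gap was smaller between the replicate 2 arrays. After quantile normalization *malK* read 10.166, 8.656 and 9.806 on wild-type replicates 1, 2 and 3, and 6.82, 7.851 and 6.535 on the mutant ones. *lamB* read 11.735, 11.038 and 11.638 against 9.106, 10.316 and 9.232. All 3 measured tryptophanase genes passed: *tnaA*, the enzyme that splits tryptophan into indole, pyruvate and ammonia, fell by 2.33 (SE 0.434), its leader gene *tnaC* fell by 1.86 (SE 0.517) and the permease gene *tnaB* fell by 0.67 (SE 0.0802). Wild type replicate 2 stood apart, with *tnaA* at 10.91 against 12.61 and 12.53 on the other wild-type arrays and *tnaC* at 10.34 against 12.32 and 12.19 after quantile normalization. Without any single array other than that one, *tnaC* did not pass and 2 of the 3 fell. In camera the tryptophanase list had an adjusted p of 0.0372, but adjusted p = 0.787 with an estimated correlation, and adjusted p = 0.111 with the values as deposited. Without wild type replicate 3 it did not pass either (adjusted p = 0.0646). Of 61 measured sugar and polyol uptake genes, 12 fell, 7 rose and 42 did not pass (camera adjusted p = 0.195, but adjusted p = 0.0204 without wild type replicate 2). The number that fell ranged from 7 without wild type replicate 1 to 19 without wild type replicate 2, and 4 rose without mutant replicate 1 or 3. Among those that rose was *araH*, a permease gene of arabinose uptake (1.43, SE 0.175). Of the 61 genes, 26 fell and 2 rose with the values as deposited, and 25 fell and 0 rose with control centring. Decreases to mutant signals below the foreign control median were those of *dcuD* (-2.54, SE 0.253, and -1.21 counted to that median), a putative C4-dicarboxylate carrier gene, *acrF* (-2.07, SE 0.209) of a multidrug efflux pump, *rclB* (-1.93, SE 0.193, and -0.2 counted likewise) of the reactive chlorine response, *ygeH* (-1.62, SE 0.285) and *yibG* (-1.60, SE 0.480), all with adjusted p at or under 0.0467. For *acrF*, *ygeH* and *yibG* the wild-type mean also lay below that mutant median, so no decrease could be counted to it. *yibG* was no longer past the threshold once the trend on signal and origin distance was removed (-0.88, adjusted p = 0.0785).

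Of 61 measured general stress genes, 15 fell, 4 rose and 42 did not pass, and the list's camera adjusted p was 0.0715, under the threshold instead with the values as deposited (0.00194), with median centring (0.00464), with control centring (0.0444) and with the signal and position trend removed (0.00093). With an estimated correlation it was adjusted p = 0.787. The largest decrease was that of *aidB* (-1.65, SE 0.269), an adaptive response gene for alkylation damage, followed by *yhcO* (-0.87, SE 0.135). *dgcM* (1.18, SE 0.242), a diguanylate cyclase gene, and *narU* (0.83, SE 0.196), a nitrate transporter gene (-0.15 with control centring), went the other way, and *dgcM* lies in a chromosomal stretch described below with low wild-type signals. The number that fell was 7 and 8 without wild type replicates 1 and 3, 6 and 4 without mutant replicates 1 and 3, and 11 and 12 without replicate 2 of the wild type and of the mutant, where the list passed in camera (adjusted p = 0.0344 and 0.0429). Only 1 or 2 rose without wild type replicate 1 or without any single mutant array. Under other scalings more of the 61 fell: 43, with 1 higher, in the values as deposited, and 26, with 0 higher, with control centring. Of 25 osmoprotection and trehalose genes, 3 fell and 5 rose (camera adjusted p = 0.899; 11 fell and 1 rose with the values as deposited, and 2 to 5 rose and 1 to 4 fell without single arrays), with *osmY*, a periplasmic protein gene widely used as an RpoS reporter, lower by -0.75 (SE 0.0813) and *proP* of proline and betaine uptake at -0.66 (SE 0.183). In the pentose phosphate pathway, *talA* (-0.76, SE 0.118) and *tktB* (-0.53, SE 0.125), the RpoS-dependent transaldolase and transketolase genes, fell, 2 of 12 members rose and 8 did not pass (camera adjusted p = 0.730), but 0 rose with the values as deposited or without any single array, and 1 fell without wild type replicate 1, wild type replicate 3 or mutant replicate 3.

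After quantile normalization, acid and oxidative stress genes showed decreases in a minority of members. Of 24 acid resistance genes, 8 fell, 1 rose and 15 did not pass (camera adjusted p = 0.175). Among those that fell were *dctR* (-1.14, SE 0.349), *gadE*, the activator gene of glutamate-dependent acid resistance (-0.71, SE 0.199), and *gadB*, a glutamate decarboxylase gene (-0.61, SE 0.168), whose mutant signals below the foreign control median leave their sizes uncertain and without order. Adjusted over the list alone, 9 fell and 2 rose. With the values as deposited, 17 of the 24 fell and 0 rose (camera adjusted p = 0.02), and with control centring 15 fell and 0 rose. After removal of the signal and position trend, 4 of the 24 were lower and 4 higher. *gadE* was then at -0.15 (limma adjusted p = 0.331), *dctR* at -0.48 (adjusted p = 0.162) and *gadB* at -0.87 (adjusted p = 0.0316). Without wild type replicate 1 or without wild type replicate 2, 0 members of the acid resistance list passed, and without any other single array 1 to 5 fell. Of 31 oxidative stress defence genes, 4 fell and 0 rose (camera adjusted p = 0.730; 3 fell when adjusted over the list alone, 1 without wild type replicate 1, mutant replicate 1 or mutant replicate 3, and 2 without wild type replicate 3): *sufE* (-0.74, SE 0.132) and *sufB* (-0.67, SE 0.195) of iron-sulphur cluster assembly, the catalase gene *katG* (-0.36, SE 0.0774) and *hemH* (-0.36, SE 0.0825). With the values as deposited, 11 of the 31 oxidative stress genes fell and 0 rose, and with control centring 7 fell and 0 rose. After quantile normalization that list's median, 0.03, and its mean, -0.04, differed in sign.

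Iron acquisition genes fell more broadly than any other list of more than 3 genes. Of 40 measured members, 23 fell, 1 rose and 16 did not pass, and adjusted over the list alone 31 fell and 1 rose (median change -0.60, camera adjusted p = 5.56e-10, but adjusted p = 0.787 with an estimated correlation). *fhuF*, a ferric siderophore reductase gene, fell by 1.46 (SE 0.288), *fepD* of enterobactin uptake by 1.12 (SE 0.110), *entB* of enterobactin synthesis by 1.12 (SE 0.219) and *cirA*, a catecholate receptor gene, by 1.06 (SE 0.173). The member that rose was the ferritin gene *ftnA*, an iron store rather than an uptake gene (1.004), named after its value was seen. Without single arrays, 13 members were lower without wild type replicate 1 or mutant replicate 3, 15 without mutant replicate 1, and between 16 and 30 otherwise. The heat shock list had as large a share lower, or a larger one, without wild type replicate 1 (7 of 20). The same held without wild type replicate 3, mutant replicate 1 or mutant replicate 3 (8 of 20 each). No test compared the lists with each other.

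Of 20 measured heat shock chaperone and protease genes, 9 fell, 1 rose and 10 did not pass, with 10 and 1 when adjusted over the list alone (camera adjusted p = 0.000308, but adjusted p = 0.787 with an estimated correlation and adjusted p = 0.0517 with control centring). The chaperonin genes *groL* (-1.50, SE 0.161) and *groS* (-1.20, SE 0.131) fell most, then *htpG*, the gene of the Hsp90 homologue (-0.71, SE 0.121), and the protease gene *hslU* (-0.70, SE 0.0969). None rose without wild type replicate 2, wild type replicate 3, mutant replicate 1 or mutant replicate 3. Of 21 envelope stress genes, 4 fell and 1 rose (camera adjusted p = 0.575), led by *rpoE*, the envelope stress sigma factor gene (0.49, SE 0.119, and -0.03 with control centring), and *cpxP* (-0.42, SE 0.101). Removal of the signal and position trend left 0 of that list lower and 1 higher, and 0 were lower without wild type replicate 1, wild type replicate 3, mutant replicate 1 or mutant replicate 3 and 2 without either other array. None rose without mutant replicate 1 or 3, and 2 rose without mutant replicate 2. None of 7 phage shock genes passed (camera adjusted p = 0.670), the largest value being that of *pspG* (-0.31, SE 0.109).

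**Figure D2:**
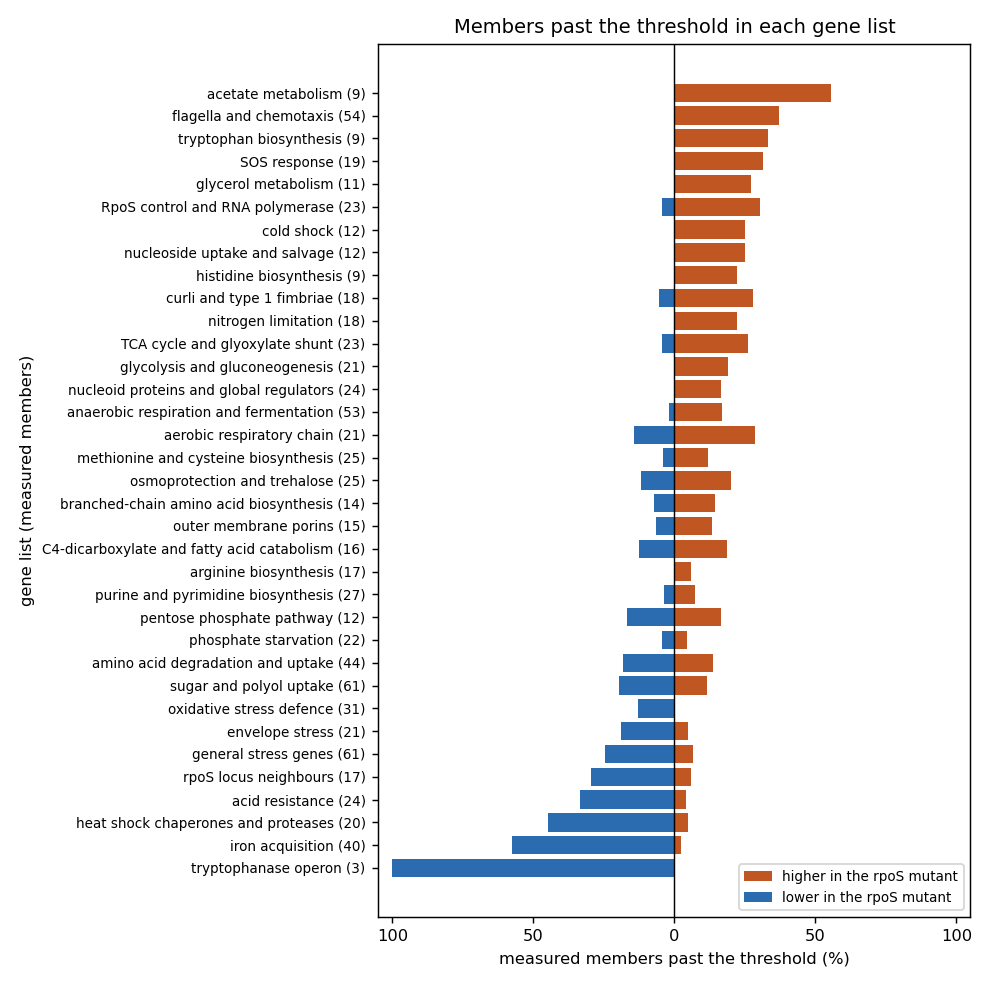
Share of measured members past the threshold (horizontal axis, %) in the 35 gene lists with at least 1 such member, higher in the rpoS mutant to the right and lower to the left, with the number of measured members in parentheses. Iron acquisition (23 of 40) and heat shock genes (9 of 20) lie to the left and flagella and chemotaxis genes (20 of 54) to the right. With centring on control probe sets nearly all calls lay to the left, and the right held 3 flagellar, 3 TCA cycle, 1 curli and fimbriae and 1 regulator gene. In camera 13 lists that did not pass after quantile normalization passed with the values as deposited, where the median of all genes was lower.

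Some motility genes rose. Of 54 measured flagella and chemotaxis genes, 20 rose, 0 fell and 34 did not pass, and 24 rose when adjusted over the list alone (median change 0.41, camera adjusted p = 7.95e-08, but adjusted p = 0.85 with an estimated correlation and adjusted p = 0.107 in fry). *ycgR*, encoding a flagellar brake that binds cyclic di-GMP, rose by 1.62 (SE 0.189), the chemoreceptor gene *tap* by 1.55 (SE 0.234), the motor gene *motB* by 1.498 (SE 0.268) and *pdeH*, a cyclic di-GMP phosphodiesterase gene, by 1.26 (SE 0.209). The genes of the flagellar master regulator, *flhD* and *flhC*, named after their values were seen, rose by 1.001 and 0.987. With control centring 3 members were higher and 0 lower, and the list's median then was 0.56 above that of all genes. Without mutant replicate 1 or without mutant replicate 3, 10 members rose. Of 18 curli and type 1 fimbriae genes, 5 rose, 1 fell and 12 did not pass (camera adjusted p = 0.163), but 3 rose and 9 fell with the values as deposited, and the list's median relative to all genes turned from 0.25 to -0.09. Without mutant replicate 3, 3 members rose, and without wild type replicate 2 the list passed in camera (adjusted p = 0.0344). The changes were led by *fimI* (1.61, SE 0.191), the major fimbrial subunit gene *fimA* (1.34, SE 0.0827) and the chaperone gene *fimC* (0.98, SE 0.111), while *bcsA* of cellulose synthesis fell (-0.60, SE 0.163).

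Succinate dehydrogenase and some cytochrome *bo* oxidase genes rose. In the TCA cycle list, 6 of 23 members rose, 1 fell and 16 did not pass, and *sdhC* (1.60, SE 0.163), *sdhB* (1.45, SE 0.251), *sdhD* (1.39, SE 0.149) and *sdhA* (0.93, SE 0.187) were the foremost (camera adjusted p = 0.652; the list's median was -0.03 and its mean 0.17). Without wild type replicate 2 the list had 5 higher and 6 lower, and with control centring 3 higher and 5 lower. In the aerobic respiratory chain, 6 of 21 genes rose and 3 fell (4 when adjusted over the list alone; camera adjusted p = 0.652), with *cyoC* at 0.64 (SE 0.0956) and *cyoD* at 0.59 (SE 0.0832). That count of increases was 2 without wild type replicate 1 or mutant replicate 3, 3 without mutant replicate 1 and 10 without mutant replicate 2, and control centring gave 0 higher and 1 lower. Decreases numbered 1 without wild type replicate 1, wild type replicate 3 or mutant replicate 1 and 0 without mutant replicate 3. Of 53 anaerobic respiration and fermentation genes, 9 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.482), and 0 rose and 19 fell with the values as deposited. Leaving out wild type replicate 1 or mutant replicate 1 gave 4 higher, and leaving out mutant replicate 3 gave 2, while 2 fell without wild type replicate 3 or mutant replicate 1. *nrfB* of nitrite reduction, the one that fell, changed by -0.84 (SE 0.164). None of 9 ATP synthase genes passed (camera adjusted p = 0.575), *atpC* having a value of -0.23 (SE 0.1235, and 0.07 with median centring).

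Central carbon genes that rose included *aceF*, *lpd* and *aceE* of the pyruvate dehydrogenase complex (0.60, SE 0.128; 0.46, SE 0.0729; 0.42, SE 0.0894), among 4 of 21 glycolysis and gluconeogenesis genes that rose and 0 that fell (camera adjusted p = 0.760). These 3 also belong to the acetate list, in which 5 of 9 rose and 0 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.146), with *pta*, phosphotransacetylase, at 0.49 (SE 0.106). Without wild type replicate 1, mutant replicate 1 or mutant replicate 3, 1 gene rose in either list, and with control centring 0 rose, with 1 lower in glycolysis and 2 in acetate metabolism. Of 11 glycerol metabolism genes, 3 rose and 0 fell (4 and 0 adjusted over the list alone), namely the facilitator gene *glpF* (1.42, SE 0.353), *glpQ* (1.06, SE 0.190) and *glpT* (1.001, SE 0.224), with a camera adjusted p of 0.0715. The number was 1 without mutant replicate 1 or 3, 5 without mutant replicate 2 and 0 with control centring. The list passed in camera without mutant replicate 2 (adjusted p = 0.00132) and with the signal and position trend removed (adjusted p = 0.0223). In C4-dicarboxylate and fatty acid catabolism, 3 of 16 rose and 2 fell (camera adjusted p = 0.834), led by the dicarboxylate carrier gene *dctA* (1.08, SE 0.202), against 2 higher and 7 lower with the values as deposited, and 1 fell without any array other than wild type replicate 2. That list's median (0.01) and mean (0.03) lay above 0 although camera placed it lower. Nucleoside uptake and salvage genes showed 3 increases and 0 decreases among 12 (camera adjusted p = 0.227), in *cdd*, cytidine deaminase (0.94, SE 0.166), *nupC*, a nucleoside permease (0.81, SE 0.190), and *deoC* (0.61, SE 0.172). This became 1 increase without wild type replicate 2, wild type replicate 3, mutant replicate 1 or mutant replicate 3, 6 without mutant replicate 2 (camera adjusted p = 0.0429) and 0 with control centring.

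Amino acid and nucleotide genes changed in both directions. Of 44 genes of amino acid degradation and uptake, 6 rose and 8 fell (10 and 10 adjusted over the list alone, camera adjusted p = 0.899), with *dadX* (1.17, SE 0.133) and *dadA* (1.01, SE 0.155) of alanine breakdown rising and *tdcA*, the activator gene of threonine breakdown, falling (-0.98, SE 0.142, and -0.2 counted to the foreign control median). In biosynthesis, 3 of 9 tryptophan genes rose and 0 fell, the largest change being that of *trpC* (0.48, SE 0.0853), but none passed after removal of the signal and position trend, and *trpC* lay at -0.08 with the values as deposited. Histidine genes gave 2 of 9 higher and 0 lower (3 and 1 adjusted over the list alone), led by *hisD* (0.72, SE 0.1205), branched-chain genes 2 of 14 higher and 1 lower, led by *ilvB* (0.58, SE 0.137), and arginine genes 1 of 17 higher, *artM* (0.30, SE 0.0707; 0 adjusted over the list alone). Of 25 methionine and cysteine genes, 3 rose and 1 fell, *cysC* (-0.59, SE 0.148), and of 27 purine and pyrimidine genes 2 rose and 1 fell (1 and 1 adjusted over the list alone), *pyrB* (-0.53, SE 0.0970). With control centring *trpC*, *hisD*, *ilvB* and *artM* lay below 0. As deposited, 17 degradation genes fell and 2 rose, and 4 tryptophan, 4 branched-chain, 6 arginine, 7 methionine and cysteine and 7 purine and pyrimidine genes fell. Without wild type replicate 1 or mutant replicate 3, 2 degradation genes rose and 2 fell. Their increases numbered 3 without wild type replicate 3 and 2 without mutant replicate 1, and their decreases 5 without mutant replicate 2. Leaving out mutant replicate 3, 1 tryptophan, 1 histidine, 1 methionine and cysteine, 0 arginine and 0 purine and pyrimidine genes rose. Purine and pyrimidine and arginine increases numbered 0 also without wild type replicate 1 or 3, and branched-chain increases 0 without wild type replicate 1 or mutant replicate 1 and 1 without any other array. The purine and pyrimidine list had 1 increase without wild type replicate 2 or mutant replicate 1 and 2 decreases without wild type replicate 3. No branched-chain gene fell without any array other than wild type replicate 2. The methionine and cysteine decreases numbered 0 without wild type replicate 2, wild type replicate 3, mutant replicate 1 or mutant replicate 3. Camera adjusted p was 0.482 for tryptophan, 0.144 for histidine, 0.918 for branched-chain, 0.880 for arginine, 0.652 for methionine and cysteine and 0.504 for purine and pyrimidine genes.

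No ribosomal protein gene passed. All 54 were measured, with a median change of -0.005, a mean of 0.02 and *rplT* at 0.23 (SE 0.0998, adjusted p = 0.121) as the largest change. limma called 0 of them also with the values as deposited. The camera adjusted p was 0.884, and 6.04e-08 with the values as deposited, where the median of all genes was lower. None of 10 translation factor genes passed, *prfA* having a value of 0.22 (SE 0.0705, and -0.01 with the values as deposited; camera adjusted p = 0.652), and none of 6 ribosome hibernation genes, *rmf* having a value of -0.27 (SE 0.0993, camera adjusted p = 0.638).

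Increases among further regulatory and stress genes depended on the scaling. The SOS response to DNA damage had 6 of 19 members higher and 0 lower (camera adjusted p = 0.0537, and 0.0305 after removal of the signal and position trend, with 3 higher), but 0 higher and 2 lower with the values as deposited, 0 and 3 with control centring, and 3 higher without mutant replicate 1, 2 or 3. It passed in camera without wild type replicate 1, wild type replicate 2 or mutant replicate 2 (adjusted p = 0.0496, 0.0344 and 0.0408). *umuC* of translesion synthesis lay at 0.72 (SE 0.106). Cold shock genes gave 3 of 12 higher and 0 lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.638), with *cspB* at 0.96 (SE 0.163). Nitrogen limitation genes gave 4 of 18 higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.0715, and adjusted p = 0.0374 without mutant replicate 2), with the regulator gene *nac* at 0.91 (SE 0.139). Of 22 phosphate starvation genes, 1 rose, *phoH* (0.45, SE 0.107), and 1 fell, with 0 when adjusted over the list alone (camera adjusted p = 0.498). *umuC*, *cspB*, *nac* and *phoH* lay below 0 when arrays were centred on control probe sets. As deposited, 0 cold shock, nitrogen limitation or phosphate genes rose, while 4, 1 and 6 fell. Without wild type replicate 1 or 2, 1 cold shock gene rose, and without mutant replicate 2, 2 cold shock and 5 phosphate genes fell. No phosphate gene rose without wild type replicate 1 or without any single mutant array, and none fell without wild type replicate 2, wild type replicate 3 or mutant replicate 3. Of 23 genes that control RpoS or belong to RNA polymerase, 7 rose and 1 fell (camera adjusted p = 0.164), with 2 and 3 in the values as deposited, and 4 higher without wild type replicate 3 or mutant replicate 1 and 3 without mutant replicate 3. *iraP*, the gene of an anti-adaptor that protects RpoS from proteolysis, rose by 1.07 (SE 0.107), and *fecI*, the iron citrate sigma factor gene, fell (-0.89, SE 0.0935). Of 24 nucleoid protein and global regulator genes, 4 rose and 0 fell (camera adjusted p = 0.108; 2 and 3 as deposited, and 2 higher without mutant replicate 3), led by *fnr* and, well behind it, *lrp* of leucine-responsive regulation (0.78, SE 0.204). Outer membrane porin genes had 2 of 15 higher and 1 lower, the latter being *lamB* (camera adjusted p = 0.669; 0 higher and 3 lower as deposited; 1 higher without mutant replicate 1; median 0.09, mean -0.004).

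Large increases lay in a single chromosomal stretch. From *ynaJ* to *ttcA*, 13 neighbouring genes, 11 rose and 2 did not pass, and among those that rose were the zinc transporter gene *zntB* (5.19, SE 0.369, and 2.1 counted from the foreign control median), the universal stress protein gene *uspE* (3.998, SE 0.1055, and 3.04 counted likewise), the tRNA thiolation gene *ttcA* (3.21, SE 0.328) and *fnr*, the regulator of anaerobic metabolism (2.99, SE 0.157). After quantile normalization, the median wild-type signal of the 13 genes was 7.007, against 9.235 for all genes, and their median mutant signal was 8.942. On the deposited arrays, *zntB* read 2.03, 2.18 and 3.53 in the wild type against 7.33, 7.68 and 7.39 in the mutant. *fnr* read 8.501, 8.404 and 8.68 against 11.14, 11.48 and 11.22. The median change of the 13 genes was 1.43, and no other run of 13 neighbours outside the stretch had a median over 1.001. Extended to *ydbK*, which takes in the cryptic prophage Rac, 30 of 40 genes rose and 0 fell, among them *rcbA* (1.97, SE 0.296), *ralR* (1.85, SE 0.264), *intR* (1.72, SE 0.144) and *recE* (1.64, SE 0.215). Part of this extension depended on the scaling, in genes chosen after their values were seen. As deposited, 8 of a run of 11 from *dgcM* to *racC* passed as higher, but 0 of a run of 4 from *ydaY* to *insH5*. *ompN* read 7.263, 7.235 and 7.332 on the deposited wild-type arrays against 7.215, 6.96 and 7.064 in the mutant. The comparison with genes of matched signal given below covers only the 13 genes. For 3 Rac genes chosen after their values were seen, the wild-type arrays disagreed: the repressor gene *racR* read 3.14, 8.12 and 3.01, *kilR* 3.401, 7.995 and 4.048, and *sieB* 0, 6.71 and 2.49 on wild-type replicates 1, 2 and 3, and none of them passed. Increases outside the stretch included *grcA*, a spare glycyl radical subunit gene (1.69, SE 0.166), and *flxA* of the Qin prophage (1.67, SE 0.181). Without the genes from *ynaJ* to *ydbK*, 1096 genes passed.

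**Figure D3:**
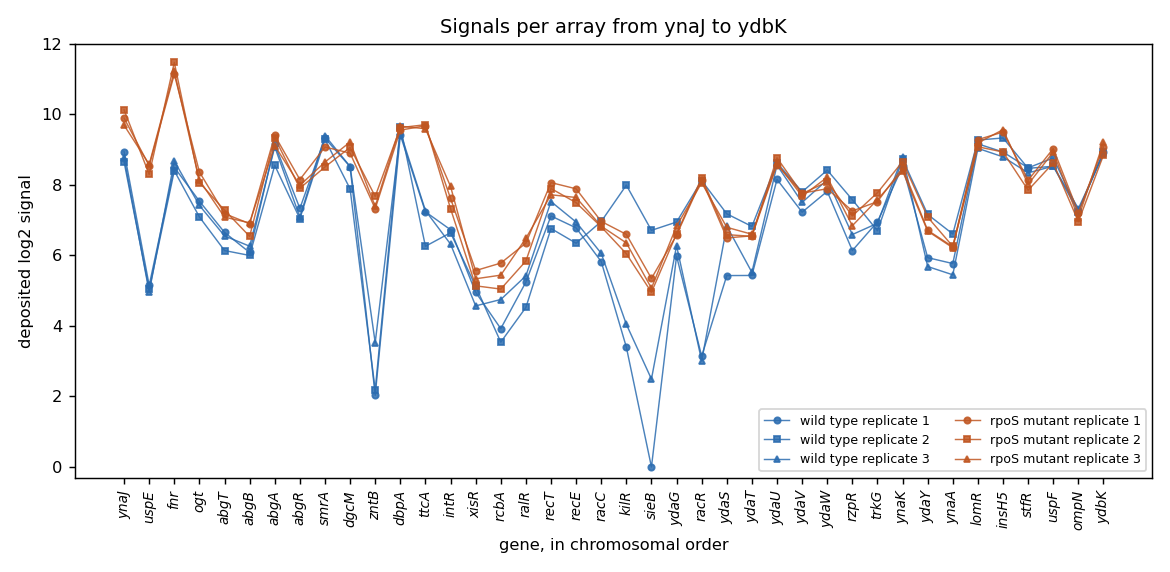
Deposited log2 signal (vertical axis) of the 40 genes from ynaJ to ydbK in chromosomal order on each of the 6 arrays, wild type in blue and rpoS mutant in orange. All 3 wild-type arrays dip at uspE, zntB and ttcA, and wild-type replicates 1 and 3, but not replicate 2, dip at kilR, sieB and racR.

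**Figure D4:**
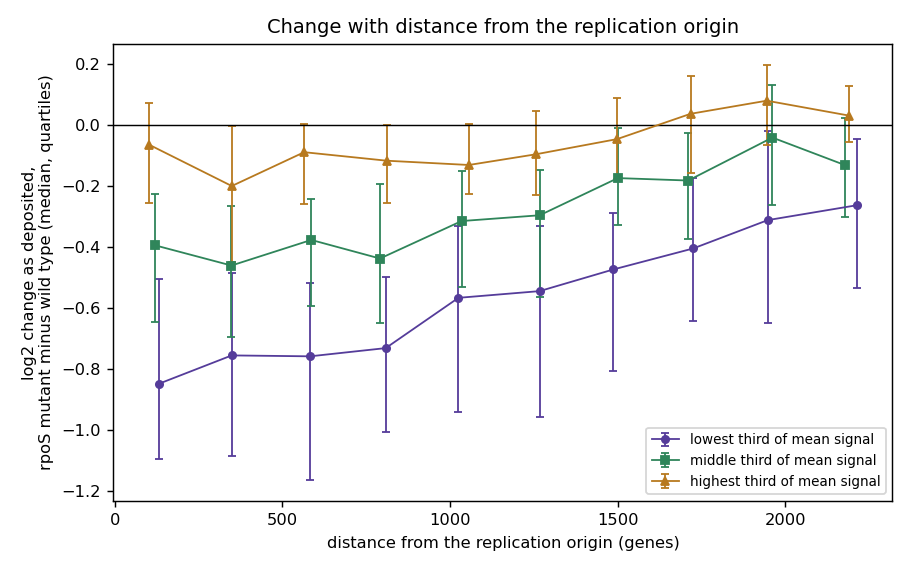
Median log2 change of the deposited values (vertical axis, rpoS mutant minus wild type) against distance from the replication origin in gene order (horizontal axis, number of genes), in 10 bins for each of 3 classes of mean signal, with bars from the lower to the upper quartile. In the class of lowest signal the median ran from -0.85 in the nearest bin to -0.26 in the farthest.

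Of 2886 intergenic probe sets, 1037 passed, 596 lower and 441 higher in the mutant, and with the values as deposited 1501 were lower and 78 higher. Within the stretch from *ynaJ* to *ydbK*, several probe sets had wild-type signals far below the foreign control median of 5.65, so their increases have no exact size. One with a wild-type mean of 0.75 and a mutant mean of 10.49 (adjusted p = 3.27e-07), an increase of 4.84 counted from that median, is placed by its identifier at 1409973 to 1410023, on a build not given in the sources used here. The one matched to *mcaS*, a small RNA gene, rose from a wild-type mean of 4.1 to 8.15, an increase of 2.5 counted likewise. Elsewhere, the probe set matched to *ybdZ*, a small gene of the enterobactin cluster, fell by 1.38 (SE 0.117). The intergenic probe sets described here were chosen after their values were seen.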

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

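The comparison of foreign with matched probe sets was chosen after its result was seen, and the test on bright genes was added once the value for dim genes was known, before its own. Probe sets outside the comparisons carried signal that differed between the strains after quantile normalization: 27 of 50 foreign control probe sets were higher on the mutant arrays and 0 lower, as were 14 of 31 other control probe sets, and of 153 gene probe sets without a single gene 8 were higher and 20 lower. With the values as deposited, the foreign probe sets had a median change of 0.396, against -0.696 for *E. coli* genes of matched signal. The former rested largely on wild type replicate 2, without which it was 0.188, and the foreign median of wild type replicate 3, 6.295, exceeded those of mutant replicates 1 and 3.

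In a broader pattern, dim *E. coli* probe sets were lower on the mutant arrays as deposited, with median changes of -0.506 in the class of lowest gene signal, -0.29 in the middle and -0.065 in the highest. A scale or background of the whole array would move foreign probe sets alike, and they lay 1.092 above matched genes (95% interval 0.919 to 1.287). The interval rests on 50 foreign probe sets that share the same arrays, so it does not measure the spread between arrays. Without single arrays the difference ran from 0.798 (wild type replicate 2), outside that interval, to 1.281 (wild type replicate 3). It kept its sign, which argues against a scale or background of the whole array as the only source. No test took the arrays as units. Residual genomic DNA in the wild-type preparations, which would be richest near the origin, may contribute, since the change of 1353 dim genes rose with distance from the origin (Spearman rho 0.404, one-sided circular-shift p = 0.0409). Different gene dosage in the cultures, for example through growth rate, could do so too, since the brightest genes followed the distance with a rho of 0.266. These explanations remain open, alone or together, as does an effect of the *rpoS* deletion on them, which was not tested.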

How the results depend on the processing

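The values as deposited, the centring on control probe sets, the removal of the *ynaJ* to *ydbK* genes, the quantile normalization over gene probe sets alone and the removal of the signal and position trend were chosen after the data had been seen, the other alternatives earlier. *rpoS* itself was lower and past the threshold under each alternative for which its level was recorded, at between -2.25 and -3.144. Its level was not recorded for the joint adjustment of genes and intergenic probe sets, for all probe sets kept or for the 2-fold requirement. Arrays limit what dim genes can show, since 29 genes past the threshold had both strains' mean signals under 6.22. That is the median of the foreign probe sets pooled over all 6 arrays, not the separate medians per strain used in the Results. The balance of directions moved with the scaling, and the cause was not tested. With the values as deposited there were 1735 genes (1615 lower, 120 higher), 1579 intergenic probe sets (1501 lower, 78 higher) and 16 gene lists past the threshold. Median centring gave 919 genes higher, 1006 intergenic probe sets lower and 16 lists, and control probe set centring gave 1245 genes lower and 16 higher, 1408 intergenic probe sets lower and 19 higher, and 13 lists. Of the 1119 genes, 642 passed in the same direction with the values as deposited, 857 with median centring, 508 with control centring and 704 with the signal and position trend removed. Array weights gave 8 lists and trend removal 7, and the cause was not tested. Asking for a 2-fold change left 113 genes (51 lower, 62 higher) by construction. Camera with an estimated correlation passed 0 lists, with no adjusted p under 0.787, and fry 13. Of the 4 lists that passed camera after quantile normalization, 1 did not pass fry, flagella and chemotaxis (fry adjusted p = 0.107). Iron acquisition, heat shock and tryptophanase did (fry adjusted p = 0.037, 0.0237 and 0.00902).

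A replicate block left 409 genes (184 lower, 225 higher) and 360 intergenic probe sets (184 lower, 176 higher), with fewer degrees of freedom. The numbers do not pair the samples: same-numbered arrays of the strains had correlations of their deviations of 0.152, -0.17 and -0.185. Without single arrays, which leaves fewer samples, there were between 507 and 874 genes (lower 229 to 422, higher 278 to 452), between 557 and 799 intergenic probe sets (lower 308 to 472, higher 249 to 327) and between 3 and 9 lists. There were fewest genes without mutant replicate 3.

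Some named genes changed sign, and the cause was not tested. As deposited, *trpC* was at -0.076 and *prfA* at -0.01, and with median centring *nlpD* was at 0.159 and *atpC* at 0.068. *ubiX*, near 0, was at 0.02 with array weights and between -0.111 and 0.093 without single arrays. With control probe set centring, which leaned on wild type replicate 2, the values were *ubiD* -0.064, *narU* -0.151, *umuC* -0.227, *cspB* -0.132, *trpC* -0.447, *ilvB* -0.135, *artM* -0.3, *phoH* -0.351, *nac* -0.2, *rpoE* -0.026, *hisD* -0.03, *rplT* -0.13 and *prfA* -0.381. Other values of named genes kept their direction, 1674 of them on the same side of the threshold, 204 no longer past it and 21 newly past it.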

Other observations

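The tests of the stretch and of the FNR-activated genes were chosen after their results were seen, and the counts of other splits were planned. Runs of neighbouring genes past the threshold in the same direction, some with members of the lists, were picked after their values were seen, so their direction and median test no gene group. A run of 6 genes that fell held *yzgL*, *glgP*, *glgA*, *glgC*, *glgX* and *glgB* (median -0.547), a run of 4 held *ygaM* and the ribonucleotide reductase genes *nrdH*, *nrdI* and *nrdE* (median -0.686), and a run of 5 held the ferrous iron uptake genes *feoA*, *feoB* and *feoC* (median -0.518). A run of 7 that rose, from *rem* to *ydfW* in the cryptic prophage Qin, held the toxin and antitoxin genes *relE* and *relB* (median 0.93; 4 of 7 passed as deposited), and a run of 10 went from *cheB* to *flhD* (median 1.075; 10 as deposited).

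The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 1119 genes and 1037 intergenic probe sets past the threshold and the highest other split 0 of each, so 1 split of 10 reached the real count in both cases. For gene lists, 6 splits gave as many as the real 4, and the highest other split gave 11.

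For the low wild-type signal from *ynaJ* to *ttcA*, scaling between arrays was examined against genes of matched signal. As deposited, the median change of the 13 genes lay 1.296 above theirs (95% interval 1.245 to 2.952). With the signal and position trend removed, 10 of the 13 were still higher past the threshold. Genes of matched signal thus did not share the change. The 13 genes were picked for their changes in these same values, however, so an excess was built in and its interval is no test of scaling. Earlier forms of that test were replaced after their values were seen: the absolute change, whose lowest value of 0.468 with control centring missed the 0.5 required, and the change relative to all genes (1.092), which scalings by a constant per array cannot move. DNA of all 13 genes missing from the wild-type cultures stays open: their median wild-type signal lay 1.357 above that of foreign probe sets (95% interval 0.310 to 3.46), but the deleted *rpoS* itself lay 1.3 above it in the mutant, a reference added after the values were seen. The median hides 2 members, chosen after their values were seen. As deposited, *smrA* read 9.33, 9.29 and 9.40 in the wild type against 9.08, 8.51 and 8.65 in the mutant. *dbpA* read 9.42, 9.66 and 9.49 against 9.56, 9.63 and 9.67. Neither had a low wild-type signal, although after quantile normalization 11 of the 13, *dbpA* among them, were higher in the mutant. DNA of part of the stretch missing may be a candidate explanation as well, a variant of the wild-type stock: of 11 consecutive intergenic probe sets there, a run picked from its values, 5 were in the lowest 1% of wild-type signals against 0 on the mutant arrays and at most 2 in any other such run, and MG1655 stocks lacking the *fnr* region are known. An effect of the *rpoS* deletion on transcription of the stretch cannot be told apart from these, because the count of genes with wild-type signals at or below the foreign median, 2 of 13 in a test restated after the values were seen, cannot show which genes are present, and DNA of the strains was not analysed here. If the strains did differ in DNA there, none of the changes in this report, inside or outside the stretch, could be assigned to *rpoS* alone.

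If less *fnr* RNA in the wild type meant less FNR activity, FNR-activated genes might be higher in the mutant. Of 43 such genes, 11 rose, 4 fell and 28 did not pass, and the list's median change of 0.09 lay at the 91.4th percentile of 10000 random lists matched on signal (camera p = 0.166, and p = 0.533 with an estimated correlation), between the bounds set, so a lower *fnr* signal as a source of these changes stays open. The random lists were matched on signal alone. Changes also followed distance from the replication origin, so the percentile cannot separate position from FNR. Growth in shaken LB leaves it unknown how active FNR was. The intergenic probe set matched to *mcaS*, a small RNA known to activate *flhDC* translation, was higher in the mutant, by 2.5 counted from the foreign control median in the wild type, and lies in the same stretch, and no test of its bearing on the flagellar genes was made.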
